A study of Homo sapiens with 6 samples.

How the data were processed

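Gene expression was measured in Capan-1 cells, an established human pancreatic carcinoma line, on 6 Affymetrix arrays. Per the labels, 3 arrays carried RNA from cells given small interfering RNA (siRNA) against GNE (siGNE) and 3 carried RNA from cells given a control siRNA. Per the labels' protocols, the cells were transfected 2 times, 48 h apart, and harvested 72 h after the second transfection, and biotinylated cRNA was made from 300 ng of total RNA. Nothing in the sources used here says whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels do not say how many siRNAs against GNE were used.

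The deposited table holds log2 expression values for 54675 probe sets on each array, as normalized by the authors. Per the submitters' processing notes the values were made with GCRMA, a method that models background from probe sequence and gives log2 values. Its version, the chip definition and whether all 6 arrays were processed together are not given in the sources used here. The log2 scale was read from the values, which ran from 0.612 to 16.3 with array medians between 2.96 and 3.02, and probe sets were not centred. Because the background was modelled, values near the array median of about 3 are close to background. Differences that start there can understate or lose the true change, and their size is uncertain. No re-normalization was applied. Arrays have no read depth.

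Probe sets were named from the platform annotation, with symbols looked up by gene identifier in a RefSeq gene table of the GRCh38.p14 assembly, used for names only. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and no gene was named from a probe set with several. For 41043 of the 41097 the gene identifier was in the gene table. No genomic coordinates were used.

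The test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the log2 values, siGNE minus control, and Benjamini-Hochberg adjustment over 22085 probe sets. These were the probe sets with a mean over all 6 arrays above 4, without the 62 control probe sets. A change was called at an adjusted p under 0.05. The design had no replicate term, which left 4 residual degrees of freedom. The titles number the arrays 1 to 3 in both groups, and a fit with this number as a block was planned beside it, with 2 residual degrees of freedom. Whether the numbers pair the arrays was checked first, by correlating the deviations from the group means over the tested probe sets. The same-number correlations were 0.58, 0.71 and 0.83, all above the limit of 0.1 set beforehand, while different-number correlations ran from -0.64 to 0.17. The pairing therefore rests on the numbers in the titles and on this check, and blocked values stand beside a result where they change it. A difference of the GNE level was also tested with an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

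For each gene 1 probe set was used, the one with the highest mean over all arrays among those annotated to that gene alone, leaving out probe sets marked as prone to cross-hybridisation where the gene had another. This gave 10862 tested genes. There were 29 gene lists covering sialic acid and glycan synthesis, stress responses, apoptosis, the cell cycle, inflammation, metabolism, epithelial and mesenchymal markers and other cell types. The 26 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, with an estimated correlation beside it) and fry, with adjustment over the 26 lists. Camera compares a list with the other genes, and fry asks whether a list's own genes move on balance one way. Members were counted by the adjusted p over all tested probe sets and by the adjusted p over the list alone. A gene is said to pass by the first of these unless the list alone is named.

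The genes named are GNE, the 12 genes with the largest rise and the 12 with the largest fall among those passing with all siGNE values above or below all control values (filled up by the smallest unadjusted p where fewer pass, and then described as not passing), up to 4 members of each list with the smallest unadjusted p, and a fixed set of DDIT3, HSPA5, ATF4, BAX, BCL2, CDKN1A, NANS, CMAS, ST3GAL5 and ST6GAL1. A further 2 genes of that set are not analysed here. Genes named outside this rule are identified as such. Of 129 named genes, 58 had more than 1 tested probe set. Of the 98 other probe sets of these genes, 9 had the opposite sign to the one used, and none of the 9 passed with the replicate block. For 5 genes (FUT8, HSPA5, MAN2A1, WIPI1 and XPO5) another probe set passed with the block while the one used did not.

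The alternatives were no filter, a mean above 6, a floor at 4, quantile normalization, median centring, trended and robust variances, array weights, the replicate block, averaging or choosing probe sets per gene, an adjusted p under 0.1, a 2-fold minimum, an estimated correlation for the lists and leaving out each array. The design, the lists, the rule for names and these alternatives were fixed before the data were examined. The replicate block with a pair of arrays left out, and the pairing check under other filters, were added afterwards.

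The scripts were tested on simulated data with the 22085 probe sets, of which 100 changed by 1 and 100 by 2 on the log2 scale. With differences between pairs simulated, the fit without the block recovered 4% of the changes of 1 and 75% of the changes of 2, with 1 false call among 80. The fit with the block recovered 56% and 96%, with 10 false calls among 162. Principal components were computed from the tested probe sets, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.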

Results

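The data are expression profiles of Capan-1 cells, a human pancreatic carcinoma line, after silencing of GNE. GNE encodes the bifunctional epimerase and kinase that starts the synthesis of sialic acid from UDP-GlcNAc. There were 3 arrays of cells given GNE siRNA and 3 arrays of cells given a control siRNA, numbered 1 to 3 in each group. Each array gave log2 expression values for 54675 probe sets, of which 22085 were tested. The share of probe sets above 4 ran from 40.3% to 40.6% over the 6 arrays. Arrays of the same number are called a pair below, and the fit with the replicate block is the limma fit that takes this number into account.

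GNE was lower after its siRNA in all 3 pairs. The only probe set for GNE had a log2 value of 11.15 ± 0.30 in control cells and 9.27 ± 0.78 in siGNE cells (SD, n = 3 arrays each). The difference was -1.88 (SE 0.40), which leaves 27.2% of the control level. The 3 pairs stood at 15.0%, 32.8% and 40.9% of their control. The limma adjusted p was 0.131 without the block and 0.0348 with the replicate block (SE 0.29). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow.

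GNE siRNA was followed by higher expression of the integrated stress response and NRF2 lists and lower expression of the S phase and mitosis lists in limma camera with the preset correlation (adjusted p = 0.102, 0.102, 0.300 and 0.300 with an estimated correlation). The transcription factor DDIT3, also known as CHOP, rose by 2.12 (SE 0.14) on the log2 scale, or 4.34-fold, with a limma adjusted p of 0.0291. The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 rose by 2.35 (SE 0.16), 2.45 (SE 0.17) and 1.77 (SE 0.15), with limma adjusted p of 0.0291, 0.0291 and 0.0406. NIBAN1, a gene induced by cell stress, rose by 2.69 (SE 0.22) from a control value of 2.85, which is at background, with a limma adjusted p of 0.0406. With values under 4 set to 4 the NIBAN1 difference was 1.53 and did not pass without the block (limma adjusted p 0.0772, and 0.0255 with it). A probe set of the quinone reductase NQO1 (1.51) and one of the prostaglandin reductase PTGR1 (1.39) also rose, with limma adjusted p of 0.0291 and 0.0406. Those genes were picked out after their values were seen, since other probe sets represent them, at 0.94 for NQO1 and 1.45 for PTGR1, with limma adjusted p of 0.0806 and 0.0756. AKR1C1 and AKR1C2 are measured by probe sets prone to cross-hybridisation between these near-identical genes, so their separate values are uncertain.

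In all, 9 probe sets rose and 0 fell in the limma fit without the block, all 9 by at least 2-fold, and 3223 had an unadjusted p under 0.05. Independent arrays would give 1104 by chance, but the arrays are paired by number, and the other splits of the arrays gave 45 to 58 where they part all 3 pairs and 260 to 3000 where they do not. These splits mix siGNE with control arrays, which widens the spread within their groups, so they are no value for an absent change either. With the replicate block, 913 probe sets rose and 1182 fell, the 9 among them, and 206 rises and 225 falls were at least 2-fold. The 3 siGNE values lay entirely above the control values for 1854 probe sets and entirely below for 2655, together 20.4%. Chance gives 10% for independent arrays, and the other splits gave 1.81% to 2.06% where they part all 3 pairs and 3.87% to 18.9% where they do not. Leaving out any single array, control or siGNE, of number 1, 2 or 3, left 0 calls in limma without the block, with 2023 to 3508 probe sets at an unadjusted p under 0.05. Leaving out both arrays of number 1, 2 or 3 left 0 calls with the block and 5529, 5022 and 5037 probe sets at an unadjusted p under 0.05. All these fits have fewer arrays and fewer residual degrees of freedom, so their 0 calls say little about stability.

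The other genes named for their rises, by the smallest unadjusted p, did not pass without the block and rose in the limma fit with the replicate block. They were the glutathione-degrading enzyme CHAC1 (log2 difference 3.75, adjusted p with the block 0.0155), the pseudokinase TRIB3 (1.96, 0.0131), the stress-induced SESN2 (1.88, 0.0153), the cystine transporter SLC7A11 (1.88, 0.0195), the histone gene H2BC4 (1.57, 0.0230), the autophagy receptor SQSTM1 (1.35, 0.0179) and DESI2 (0.94, 0.0241). Of the falls, none passed without the block, and the 12 genes with the smallest unadjusted p there were among the 623 genes that fell with it in limma. The granin SCG2 fell by 2.34 (SE 0.22, adjusted p 0.0241), the matrix glycoprotein EFEMP1 by 1.87 (SE 0.11, adjusted p 0.0153), the kinetochore protein SPC24 by 1.86 (SE 0.18, adjusted p 0.0241) and PLAT, tissue plasminogen activator, by 1.75 (SE 0.10, adjusted p 0.0153). TXNDC16 (-1.27), WSB2 (-1.26), RABGGTA (-1.22), MAGT1 (-1.15), NRBP1 (-1.13), TEX30 (-1.06), TMEM107 (-0.94) and EHD3 (-0.90) fell with limma adjusted p between 0.0237 and 0.0281 in the same fit.

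**Figure D1:**
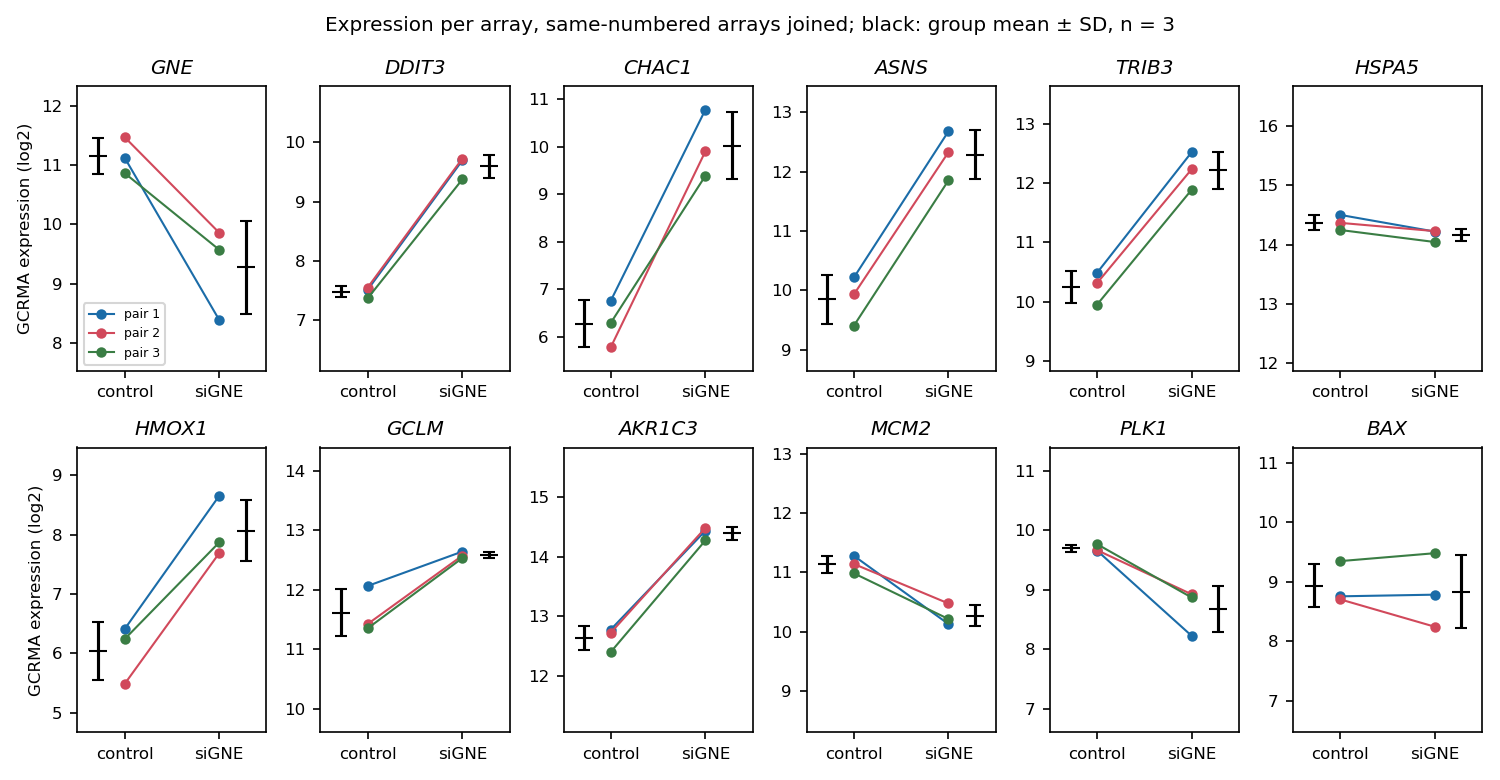
Log2 GCRMA expression of 12 genes on each of the 6 arrays, with lines joining the control and siGNE arrays of the same number and black marks for group mean ± SD (n = 3). GNE, MCM2 and PLK1 lie lower in siGNE in all 3 pairs, DDIT3, CHAC1, ASNS, TRIB3, HMOX1, GCLM and AKR1C3 lie higher in all 3, HSPA5 differs by -0.21 and BAX by -0.10, and each panel has its own range of values.

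Genes of the integrated stress response, which ATF4 and CHOP drive when translation initiation is limited, were higher as a group. Of 23 tested members of 25, 22 were higher in all 3 pairs, and the mean log2 difference was 1.25, with 1.24, 1.28 and 1.22 in the 3 pairs. Asparagine synthetase (ASNS) rose by 2.44 (SE 0.08), the serine synthesis enzyme PSAT1 by 1.66 (SE 0.09) and ATF4 itself by 0.70 (SE 0.09) in the limma fit with the replicate block, with adjusted p of 0.00813, 0.0153 and 0.0284. ASNS, PSAT1 and ATF3 were picked out after their values were seen. DDIT3 was the only member that rose without the block, 21 rose adjusted over the list alone and 20 rose with the block. ATF3 was the exception, at -0.37 with a limma adjusted p of 0.750, and it fell with the block when adjusted over the list alone (limma adjusted p 0.0216). Camera in limma gave the list an adjusted p of 7.81e-26, and adjusted p = 0.102 with an estimated correlation (0.249 with the block). Fry in limma, which tests the list's own genes only, gave an adjusted p of 0.00233.

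Target genes of NRF2, the transcription factor of the oxidative stress response, were higher in the same samples. All 18 tested members were higher in all 3 pairs, with a mean log2 difference of 1.16 and values of 0.95, 1.29 and 1.23 in the pairs. AKR1C1, AKR1C2 and AKR1C3 rose without the block, 14 members rose adjusted over the list alone and 13 rose with the block. HMOX1, the heme-degrading oxygenase, rose by 2.03 (SE 0.15), AKR1B10 by 1.74 (SE 0.24), and GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, by 1.44 (SE 0.17) and 0.97 (SE 0.15) in the limma fit with the replicate block, with adjusted p of 0.0195, 0.0303, 0.0261 and 0.0348. HMOX1, AKR1B10, GCLC and GCLM were picked out after their values were seen. PRDX1 (0.16), PGD (0.22), TALDO1 (0.24), TXN (0.34) and TKT (0.38), also picked afterwards, did not pass in either limma fit. SLC7A11 stands in this list and in that of the integrated stress response. Camera in limma gave an adjusted p of 8.30e-19, and adjusted p = 0.102 with an estimated correlation (0.556 with the block). Fry in limma gave an adjusted p of 0.00233.

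Genes of DNA replication and mitosis were lower throughout. All 27 tested S phase genes and all 28 tested mitosis genes were lower in all 3 pairs, with mean log2 differences of -0.77 and -0.67. The pairs differed in size, at -1.17, -0.58 and -0.55 for the S phase list and -1.01, -0.50 and -0.52 for the mitosis list. Of the S phase genes, 26 fell adjusted over the list alone and 13 with the replicate block, and of the mitosis genes 28 and 12, while 0 passed over all probe sets in limma without the block, where 3223 probe sets had an unadjusted p under 0.05. With the block in limma, DNA polymerase alpha (POLA1) fell by 1.82 (SE 0.30, adjusted p 0.0380), cyclin E2 (CCNE2) by 1.15 (SE 0.16, adjusted p 0.0294), and the replicative helicase subunits MCM7 and MCM2 by 0.94 and 0.86 (adjusted p 0.0367 and 0.0320). The kinetochore motor CENPE fell by 1.11, the mitotic kinases PLK1 and AURKB by 1.03 and 0.82, and KIF20A by 0.77 in the same limma fit, with adjusted p of 0.0409, 0.0344, 0.0267 and 0.0302. Camera in limma gave adjusted p of 9.10e-17 for the S phase list and 3.27e-16 for the mitosis list, and adjusted p = 0.300 for both with an estimated correlation (0.581 with the block).

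The series title connects GNE with apoptosis, and lists of apoptosis genes, p53 targets and endoplasmic reticulum (ER) chaperones were fixed for that reason. None of these lists moved as a group. The values are transcript levels, and apoptosis itself was not measured in these data. DDIT3, which rose by 2.12, stands in the integrated stress response list and in none of these. The 25 tested pro-apoptotic genes had a mean difference of 0.03 and a median of -0.04, so mean and median differ in sign, with a camera adjusted p of 0.565 in limma. Only the initiator caspase CASP9 rose with the replicate block, by 0.59 (limma adjusted p 0.0334). BAX differed by -0.10 (SE 0.35), CASP6 by -0.34 and CASP2 by -0.23, and these did not pass in either limma fit. Of 13 anti-apoptotic genes (mean -0.06, camera adjusted p 0.835 in limma), BIRC2, an inhibitor of apoptosis, fell by 0.69 with the block (limma adjusted p 0.0348), while BIRC5 (-0.58), BCL2L2 (0.38), XIAP (-0.20) and BCL2 (0.15) did not pass. BCL2 read 4.04 in control and 4.19 in siGNE cells, close to the limit of 4 for testing, where differences can be lost. Among 21 p53 target genes (mean 0.04, camera adjusted p 0.556 in limma), CDKN1A rose by 0.58 and GDF15 by 0.64, DDB2 fell by 1.01 with the block (limma adjusted p 0.0351, 0.0467 and 0.0298), and MDM2 (-0.58) and TNFRSF10B (0.48) did not pass. The CDKN1A difference was 0.52, 0.51 and 0.70 in pairs 1, 2 and 3. In fits without the block, which break a pair, it was 0.35 without the control array of number 3 and 0.32 without the siGNE array of number 1. Over all settings it ran from 0.32 to 0.87. Of 26 ER chaperone and degradation genes (mean 0.06, camera adjusted p 0.296 in limma), HERPUD1 rose by 0.80, ERN1 by 0.61 and EDEM1 by 0.50 and MANF fell by 0.43 with the block, with limma adjusted p between 0.0320 and 0.0476. The central chaperone HSPA5 differed by -0.21 (SE 0.13) and did not pass in either fit, while its other probe set, with a lower signal, fell by 0.87 with the block (limma adjusted p 0.0337).

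Apart from GNE, no gene of the sialic acid pathway or sialyltransferase lists passed over all probe sets in either limma fit. The 10 tested genes of the pathway had a mean difference of -0.13 and a median of 0.05, the 9 without GNE had a mean of 0.07, and camera in limma put the list on the higher side with an adjusted p of 0.835. Adjusted over the list alone, only GNE fell in limma without the block, and with the block GNE and NEU3 fell and SLC17A5, NEU1 and NAGK rose (limma adjusted p over the list 0.0148, 0.0455, 0.0350, 0.0455 and 0.0455). NAGK, at 0.40, was picked out after its values were seen. The next enzymes of the pathway, NANS (0.09, SE 0.18) and CMAS (0.01, SE 0.14), lay within the spread between arrays, and the sialidase NEU3 (-0.45), the lysosomal exporter SLC17A5 (0.47) and the sialidase NEU1 (0.37) did not pass over all probe sets in either limma fit. None of the 9 tested sialyltransferases passed in either limma fit (mean -0.21, camera adjusted p 0.254), with ST6GAL1 at -0.26, ST6GALNAC4 at -0.45, ST3GAL3 at -0.42, ST3GAL2 at -0.36 (from -0.60 to -0.16 with 1 array left out) and ST3GAL5 at 0.01. ST3GAL3 read 4.42 in control and 4.00 in siGNE cells, close to the limit of 4 for testing, where differences can be lost. The list built around UDP-GlcNAc synthesis was higher as a group (8 tested, mean 0.31, median 0.17, camera adjusted p 0.0130 in limma, adjusted p = 0.242 with an estimated correlation). Of its members, 6 were higher in all 3 pairs and only 1 passed with the block. This was GFPT1, the enzyme that commits fructose phosphate to UDP-GlcNAc synthesis, which rose by 1.06 (SE 0.09, limma adjusted p 0.0230). GNPDA1 (0.49), GNPDA2 (0.21) and GNPNAT1 (0.14) did not pass.

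Among 24 N-glycan processing genes (mean -0.09, camera adjusted p 0.457 in limma), the branching enzyme MGAT4B rose by 0.94 and the glucosidase MOGS fell by 0.49 with the replicate block (limma adjusted p 0.0230 and 0.0407), while FUT8 (-0.93) and MAN2A1 (-0.36) did not pass. Another probe set of FUT8 fell by 1.09 and another of MAN2A1 by 0.49 with the block (limma adjusted p 0.0370 and 0.0480). Among 15 glycosphingolipid genes, the glucosylceramide synthase UGCG fell by 0.55 with the block (limma adjusted p 0.0348), and B3GALT4 (0.56), HEXA (0.26) and CERS6 (-0.23) did not pass. In fits without the block, which break a pair, UGCG differed by -0.36 without the siGNE array of number 1. B3GALT4 differed by 0.28 without the control array of number 1. The glycosphingolipid list had a mean of -0.03, and camera in limma put it on the higher side with an adjusted p of 0.923.

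Autophagy and lysosome genes were higher as a group (17 tested, mean 0.30, camera adjusted p 0.00134 in limma, adjusted p = 0.242 with an estimated correlation). SQSTM1 rose by 1.35, MAP1LC3B by 1.03 and GABARAPL1 by 0.74 with the replicate block (limma adjusted p 0.0179, 0.0242 and 0.0298), and WIPI1 (0.68) did not pass, although another of its probe sets rose by 0.85 (limma adjusted p 0.0260). Heat shock genes (11 tested, mean 0.19) and cholesterol synthesis genes (16 tested, mean 0.20) both had a camera adjusted p of 0.0405 in limma, with adjusted p of 0.362 and 0.333 with an estimated correlation. The cholesterol list did not pass with the block (limma camera adjusted p 0.0525). DNAJB1 rose by 0.56 and HSPA4 by 0.50, and HMGCS1 rose by 0.65 and MSMO1 by 0.71, with the block (limma adjusted p 0.0325, 0.0470, 0.0361 and 0.0407), while SC5D (0.85), DHCR7 (0.24), BAG3 (0.26) and HSPH1 (0.21) did not pass.

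Mesenchymal markers were lower with the replicate block (8 tested, mean -0.45, limma camera adjusted p 0.0213, against 0.0711 without the block and adjusted p = 0.556 with the block and an estimated correlation). The matrix protein TGFBI fell by 1.13 and the calcium-binding S100A4 by 1.11 with the block (limma adjusted p 0.0343 and 0.0242), while FN1 (-0.38) and VIM (-0.18) did not pass. VIM read 4.42 in control and 4.24 in siGNE cells, close to the limit of 4 for testing, where differences can be lost. Epithelial markers had a mean of 0.05 over 20 genes (camera adjusted p 0.271 in limma), and CLDN1 (0.32), CLDN7 (0.33), KRT18 (0.20) and ESRP1 (-0.44) did not pass in either fit. Of 19 integrin and matrix adhesion genes (mean -0.07, camera adjusted p 0.835 in limma), ITGB8 fell by 0.45 with the block (limma adjusted p 0.0425), while ITGA1 (-1.07), LAMB3 (0.48) and ITGA2 (0.46) did not pass. With 1 array left out ITGA1 ran from -1.68 to -0.71 and LAMB3 from 0.20 to 0.71. Among 15 mucin and secreted epithelial genes (mean 0.13, camera adjusted p 0.142 in limma), MUC20 rose by 1.35 and MUC4 by 0.58 with the block (limma adjusted p 0.0340 and 0.0308), and MUC13 (0.43) and LCN2 (0.32) did not pass. The mean of that list was 0.363, 0.025 and 0.002 in pairs 1, 2 and 3, and ran from -0.025 to 0.253 over the settings.

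Among 19 NF-kB and cytokine genes (mean -0.25, camera adjusted p 0.150 in limma), the chemokines CXCL1 and CXCL8 fell by 1.37 and 1.26 and IL6 fell by 0.84 with the replicate block (limma adjusted p 0.0473, 0.0294 and 0.0466), and NFKBIA (-0.43) did not pass. Interferon-stimulated genes went both ways, with a mean of 0.01 and a median of 0.09 over 26 genes (camera adjusted p 0.835 in limma). OAS3 fell by 0.94, IRF9 rose by 0.71 and OAS1 rose by 0.69 with the block (limma adjusted p 0.0281, 0.0496 and 0.0431), and IFI35 (-0.54) did not pass. In the hypoxia and glycolysis list (19 tested, mean 0.08, camera adjusted p 0.457 in limma), NDRG1 rose by 1.06, ADM by 0.78 and VEGFA by 0.59 with the block (limma adjusted p 0.0259, 0.0284 and 0.0327), and EGLN3 (-0.37) did not pass. In a fit without the block, which breaks a pair, the ADM difference was 0.34 without the siGNE array of number 1. Over all settings it ran from 0.34 to 1.15.

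Of 22 genes of oxidative phosphorylation (mean -0.10, camera adjusted p 0.347 in limma), NDUFB3 fell by 0.66 with the replicate block (limma adjusted p 0.0281), and UQCRC1 (-0.31), COX7B (-0.28) and SDHA (-0.26) did not pass. Genes of the RNA interference machinery did not pass singly (10 tested, mean -0.23, camera adjusted p 0.0843 in limma), with XPO5 at -0.57, AGO1 at -0.39, DROSHA at -0.38 and TNRC6A at -0.23. Another probe set of XPO5 fell by 0.59 with the block (limma adjusted p 0.0351). None of 21 cytosolic ribosomal protein genes passed in either limma fit (mean -0.03, camera adjusted p 0.835), with RPS12, RPS3, RPL27 and RPL10A between -0.07 and -0.06. RPL27 read 15.82 in control cells and RPL10A 15.08, close to the highest values on the arrays (16.2 to 16.3), where differences can be compressed. Lists of other cell types had too few tested members for a list test. ACTA2 fell by 0.52 and COL1A1 rose by 0.71 with the block (limma adjusted p 0.0422 and 0.0441), and LYZ differed by 0.03 and did not pass. In fits without the block, which break a pair, the ACTA2 difference was -0.30 without the siGNE array of number 3. In such fits that of COL1A1 was 1.09 and 0.43 without the control arrays of number 2 and 3 and 0.47 without the siGNE array of number 2.

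**Figure D2:**
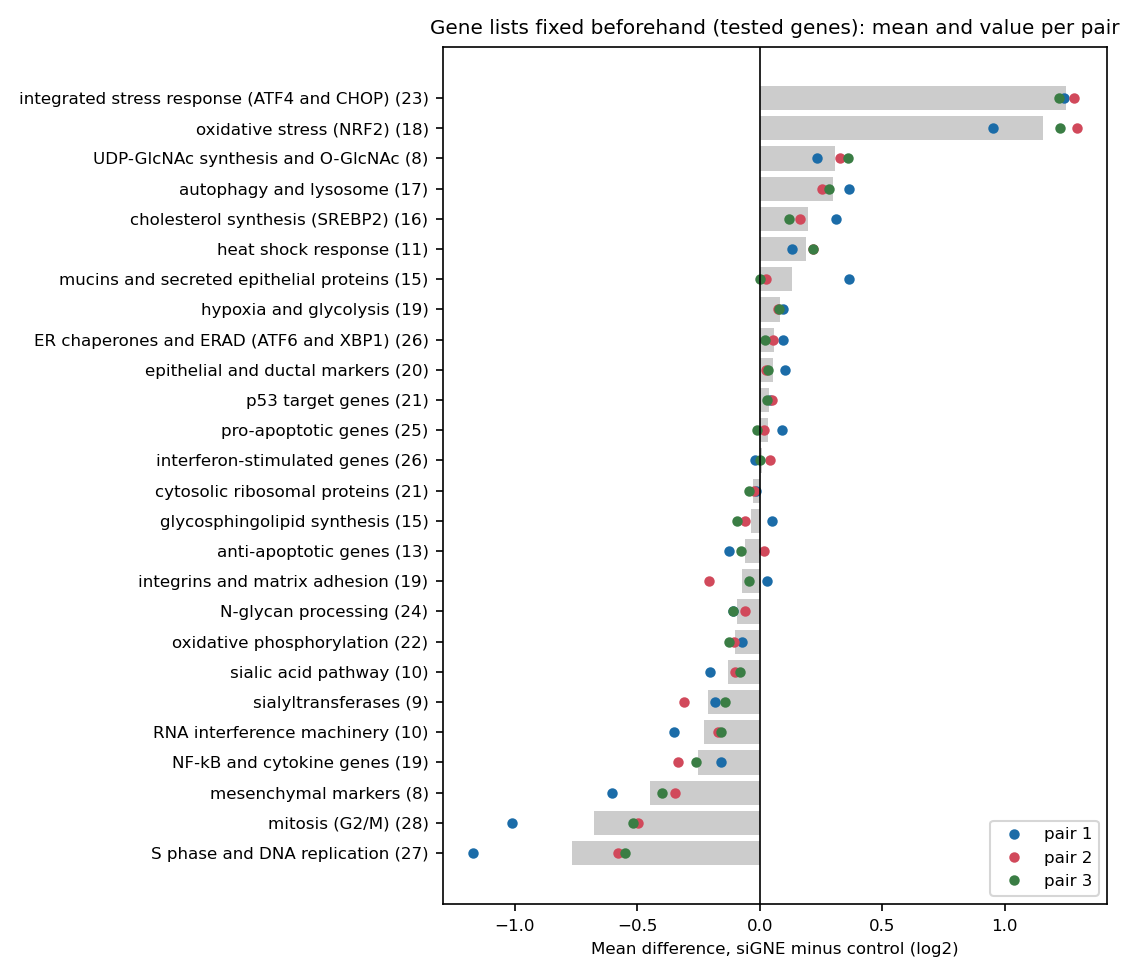
Mean log2 difference, siGNE minus control, of the tested genes of each of the 26 gene lists (grey bars, number of genes in brackets), with a point for each of the 3 pairs of same-numbered arrays. The integrated stress response (1.25) and NRF2 (1.16) lists lie highest and the mitosis (-0.67) and S phase (-0.77) lists lowest, each with all 3 pairs on the same side of 0.

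Of the 26 lists, camera in limma called 8 without the block (6 higher, 2 lower) and 8 with it (5 higher, 3 lower). Fry in limma called the integrated stress response, NRF2, UDP-GlcNAc and autophagy lists higher and the NF-kB, mesenchymal, mitosis and S phase lists lower without the block (adjusted p from 0.00233 to 0.0275). With the block it called the integrated stress response, NRF2 and hypoxia lists higher (limma adjusted p 0.00107, 0.0466 and 0.0407). With an estimated correlation camera called 0 in both fits, while 8 and 8 lists passed with the preset one. Leaving out the siGNE array of number 3 left 5 called lists.

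The arrays of number 3 stood apart from the others in both groups. The mean of the poly(A) spike-in probe sets was 6.06 and 6.14 on the control and siGNE arrays of number 3 and between 8.35 and 9.44 on the other 4 arrays. The probe set for the 5' part of 18S ribosomal RNA read 3.48 and 4.66 on these arrays and between 7.19 and 10.94 on the others. The first principal component, with 48.6% of the variance, separated number 3 from the rest, and the second, with 30.0%, separated siGNE from control. A sign of RNA quality, the difference between the 3' and 5' probe sets of ACTB, was 1.02 ± 0.46 in control and 1.08 ± 0.52 in siGNE (SD, n = 3, exact two-sided permutation p = 0.9).

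**Figure D3:**
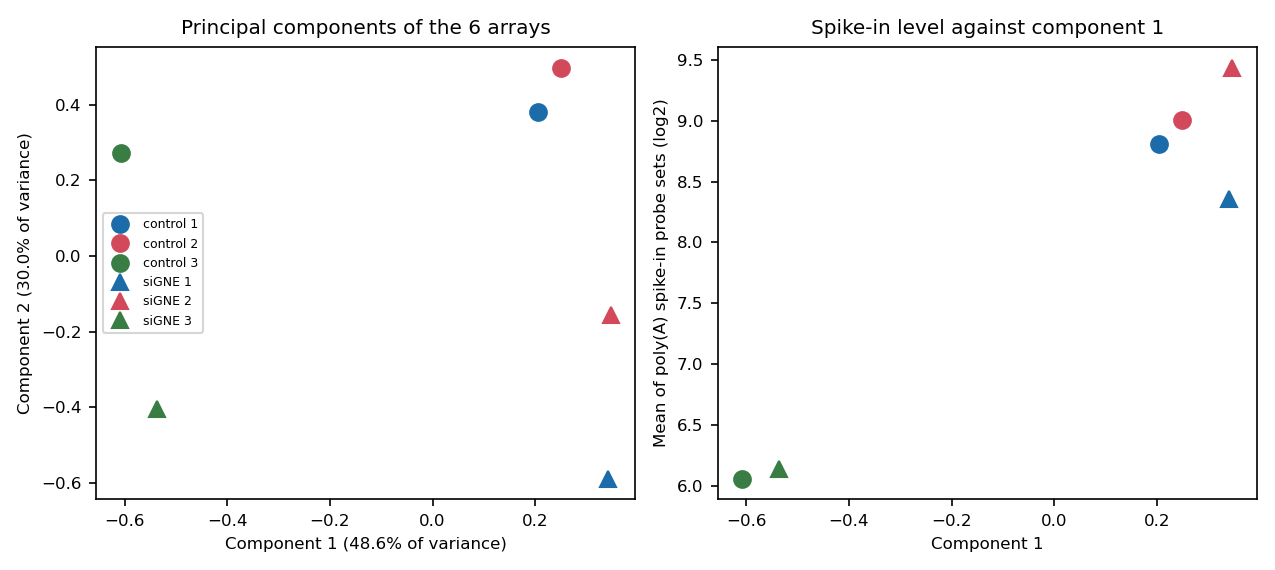
Left, scores of the 6 arrays on principal components 1 (48.6% of the variance) and 2 (30.0%). Right, the mean log2 value of the poly(A) spike-in probe sets against component 1; circles are control and triangles siGNE arrays, coloured by number, and both arrays of number 3 lie apart, at spike-in means of 6.06 and 6.14.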

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

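The replicate block with a pair left out and the same-number correlations under other settings were chosen after seeing the data, and the other settings beforehand. The number of called probe sets was 9 without the block and 2095 with the replicate block (913 up, 1182 down), and the SE of GNE (-1.88) fell from 0.40 to 0.29. It was 3 without a filter, 35 with a mean above 6, 20 after quantile normalization, 15 after median centring, 44 with trended and robust variances, 276 with array weights, 40 with probe sets averaged per gene, 75 with 1 probe set per gene and 219 at an adjusted p under 0.1. The share of rises was 142 of 276 with array weights. The 3 calls without a filter were MED7 (-0.84), NQO1 (1.51) and SOX30 (1.33), named after their values were seen. Fewer or more probe sets tested can move the adjustment, as in the filtered and per-gene settings (17580 probe sets and 10862 genes). For the others the cause was not tested. Leaving out 1 array gave 0 to 0 calls in limma, with 2023 to 3508 at an unadjusted p under 0.05. With the block, leaving out the arrays of number 1, 2 or 3 gave 0, 0 and 0 calls in limma, with 5529, 5022 and 5037 at an unadjusted p under 0.05. Those fits have fewer arrays.

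The GNE difference ran from -2.17 to -1.44 over 19 settings, with limma adjusted p from 0.0348 to 0.395, and passed only with the replicate block. Called lists ran from 5 to 12 when 1 array was left out. They were 5 without the siGNE array of number 3 and 12 without the control array of number 3. With an estimated correlation 0 lists were called. Correlation between genes does not account for all of this loss. With the block, the integrated stress response list had an estimated correlation of -0.0277, under the preset 0.01, and an adjusted p of 0.249 in limma camera. For the UDP-GlcNAc list without the block these were -0.0631 and 0.242. The integrated stress response, NRF2, S phase, mitosis and autophagy lists passed in all 19 settings with the preset correlation, UDP-GlcNAc in 18, heat shock in 13, cholesterol synthesis in 11, mesenchymal markers in 5, mucins in 3, and ER chaperones, epithelial markers and RNA interference in 1 each. Of 161 recomputed genes, 94 passed with the replicate block, and 0 of these had the other sign in any setting that tested them, which for those left out by a filter are fewer. This says little, since a call with the block already needs similar differences in all 3 pairs. Several settings, such as the trended variances, also leave the difference itself unchanged. The block brought 89 genes past the threshold and ended 0 calls. Averaging the probe sets of a gene took HSPA4 from 0.50 to 0.09, EHD3 from -0.90 to -0.46 and MUC4 from 0.58 to 0.37, and none of these passed there. Of 59 named genes that passed in neither fit, 24 moved by over 1.5 times or to the other sign when 1 array was left out. Of these, 6 moved to the other sign (BAX, BCL2, NANS, CMAS, ST3GAL5 and LYZ), so their single values carry little. Those fits had no block and break a pair, so part of the movement can be a difference between the numbers. NANS was higher in all 3 pairs (0.02, 0.13 and 0.11), while BAX, BCL2, CMAS and ST3GAL5 went both ways between pairs. The lowest same-number correlation was 0.55 to 0.59 under other filters and quantile normalization. The median difference of all tested probe sets was -0.01 as deposited, 0.01 after quantile normalization and 0.03 after median centring. Signal near background limits what low probe sets can show.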

Other observations

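The gene families, the test of the tRNA synthetases and the single genes in this paragraph and the next were chosen after the values were seen, and of the tests of explanations further on, those of a shared batch and of RNA quality were. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were higher after GNE siRNA, while their mitochondrial counterparts were not. Of 15 tested cytosolic synthetase genes, 10 rose and 1 fell in the limma fit with the replicate block, with a mean log2 difference of 0.54. WARS1 (1.11), YARS1 (1.08) and SARS1 (1.03) rose most and VARS1 fell by 0.48. AARS1, CARS1 and WARS1 are also in the integrated stress response list, and GARS1 and KARS1 serve mitochondria too. The 15 mitochondrial synthetase genes had a mean of -0.15, and only NARS2 passed, at -0.43. The difference between the families, 0.69, had a permutation p of 8.00e-05 over 100000 resamples, which compares genes, and genes are not independent replicates. Among 14 families, camera in limma gave the cytosolic synthetases an adjusted p of 1.07e-07, and adjusted p = 0.253 with an estimated correlation.

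Of 18 tested histone genes, 6 rose and 1 fell with the replicate block, among them H2BC4 (1.57) and H4C8 (1.45), while H1-10, a linker histone gene outside the histone clusters, fell by 1.12. The family mean was 0.39, with a limma camera adjusted p of 2.36e-04, and adjusted p = 0.247 with an estimated correlation. The guanylate-binding proteins GBP1, GBP2 and GBP3, known as interferon-inducible, fell by 1.52, 1.04 and 1.05 with the block (limma adjusted p 0.0256, 0.0237 and 0.0422, against 0.136, 0.369 and 0.207 without it), and the GBP2 values of the groups overlapped. As single genes, ALDH3A1 rose by 1.36 and UGT1A6 by 1.94 and EPHX2 fell by 1.06 in the same fit (limma adjusted p 0.0186, 0.0179 and 0.0237). CYP1A1 was higher from a control mean of 3.57, near background, and with values under 4 set to 4 its difference was 0.72 and did not pass (limma adjusted p 0.0659 with the block). The signs of the synthetase, histone and guanylate-binding protein families and of their called members were the same after quantile normalization and median centring. Those corrections moved almost all differences by no more than 0.055 and 0.041, so the signs could hardly have turned.

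The pair of number 1 had the lowest GNE level relative to its control, 15.0%, and the lowest S phase and mitosis means, -1.17 and -1.01. The integrated stress response mean was 1.24 in that pair and 1.28 and 1.22 in the others. The ACTB 3' minus 5' change was 0.40 in that pair and -0.20 and -0.04 in pairs 2 and 3. From control to siGNE the 5' probe set of 18S ribosomal RNA went from 10.41 to 7.19 in pair 1. It went from 10.94 to 10.09 in pair 2 and from 3.48 to 4.66 in pair 3. No relation between these values was tested.

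The fit with the replicate block called 2095 probe sets and the fit without it 9. A batch shared by arrays of the same number, such as a common day of transfection or hybridisation, is a candidate explanation, since the lowest same-number correlation of deviations was 0.576 and the highest different-number one 0.17. What the number stands for is not given in the labels. Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many as 9 called probe sets, and the highest other gave 0. Of the 4 splits that part all 3 pairs, only 1, the real one, gave as many as 2095 with the block, and the highest other gave 0. The splits are too few for a share under 0.05. All but the real split also mix siGNE with control arrays, which widens the spread within their groups, so their 0 calls are no value for an absent change. The other 6 splits put arrays of the same number on 1 side and have no matching block.

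The integrated stress response genes were higher by 1.25 on average. A difference in RNA quality stays open. The ACTB 3' minus 5' change was 0.0546 on average (SD 0.31 over the pairs), at 0.40, -0.20 and -0.04. By a rule set after the data were seen, this change of direction between pairs counts against it. But 3 pairs of 1 gene with such a spread cannot decide, and its 3' probe set read 15.5 to 15.8, near the highest values. An interferon response to the transfected RNA stays open, since the interferon-stimulated genes had a mean of 0.00834 but went both ways, with 5 rises and 2 falls with the replicate block and 10 genes higher and 9 lower in all 3 pairs. The difference in scale between arrays that quantile normalization and median centring could remove from the deposited values was small. They moved almost all differences by no more than 0.055 and 0.041. The list mean stayed at 1.26 or more, but corrections of that size could hardly have changed it, so this test cannot decide. The median of all tested probe sets moved only from -0.01 to 0.01 and 0.03. A shift that the authors' own normalization put into all values cannot be seen in normalized values and stays open. An effect of lower GNE, an off-target effect of the siRNA and other differences between the siRNAs may each be the source, because no sample with a different GNE siRNA was analysed here and the labels do not say how many siRNAs were used.

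The NRF2 target genes were higher by 1.16 on average. The AKR1C family alone does not account for this, since the list mean without it was 0.952. The same small corrections for scale between the arrays left a mean of at least 1.17, which they could hardly have changed, so that test cannot decide here either. A shift by the authors' own normalization stays open. An effect of lower GNE and an off-target effect of the siRNA may each be the source and were not tested. Of the 10 splits, 3 gave as many called lists as the real one with 8, itself included, the highest other gave 9, and the splits are too few for a share under 0.05.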
